A study of Rattus norvegicus with 12 samples.

How the data were processed

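RNA sequencing was available for 12 libraries from whole hearts of Sprague Dawley rats, an outbred laboratory stock. Per the labels, dams of the gestational diabetes (GDM) groups ate a diet rich in fat and sucrose (HFS) from before mating until the end of lactation, and Lean dams ate a low fat (LF) diet. Their offspring were weaned at 3 weeks onto LF or HFS by random assignment, and hearts were taken at 15 weeks. Groups are written as dam and offspring diet (Lean-LF, Lean-HFS, GDM-LF and GDM-HFS), with 3 libraries in each. The design text plans 6 animals per group; the other animals were not analysed here. Every library's title carries a different number, which was read as the animal's. The labels do not say which animals shared a litter, so p-values measure the spread between these samples and may not speak for separate dams.

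Per the labels, total RNA was depleted of ribosomal RNA, made into strand-marking NEBNext Ultra II libraries and sequenced in pairs of 100 bp reads on an Illumina HiSeq instrument. STAR 2.5.1b aligned the reads to Rnor_6.0, per the labels. The submitters' processing notes also name Trim Galore, FastQC, HOMER 4.9 and edgeR, without saying what each made. Coordinates are those of the deposited table.

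The deposited table holds 1 value per gene model and library. Its name calls the unit FPKM, and the tests were planned for FPKM, but the values are not divided by gene length. In each library they are whole multiples of 1 step (0.184 to 0.262), so the unit used here is a normalised read signal, as deposited: whole reads times a constant for that library. Dividing by the step gave whole reads, within 0.1 read, for 99.9994% of values. How reads were assigned to models is not given in the sources used here, and the values show it in part. Between 67.8 and 73.6% of the recovered read numbers from 1 to 40 were even, as when both mates of a pair are counted. The model of Cep85l, on the opposite strand to Pln and overlapping it, had a mean of 11019 against 10370 for Pln, with a Pearson r of 0.99958 over the 12 libraries, so strand was not used and overlapping models share reads. Of the 12980 models tested, 1374 (10.6%) overlap another model of the table, and for 1005 (7.74%) an overlapping model holds a value of at least 25% of their own. Genes with such an overlap are named as uncertain or left out, and copies in gene families or pseudogenes may also share reads. Mitochondrially encoded transcripts were not analysed here.

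Recovered reads summed over gene models came to 22661235 to 31258255 per library. Outside ribosomal RNA models the sums were 9172734 to 14418970, lowest in Lean-LF 1 and highest in GDM-HFS 1. Reads in overlapping models count more than once in these sums, such as those of the ribosomal RNA models that overlap on chromosome 14. At this depth 11443 to 12079 models had at least 10 reads in a library. The 45S ribosomal RNA model alone took 5.49 to 13.3% of each library's implied total. Its mean share was 8.89 ± 4.00% in Lean-LF, 7.96 ± 1.41% in Lean-HFS, 6.77 ± 1.11% in GDM-LF and 6.02 ± 0.313% in GDM-HFS (exact p = 0.07 for GDM against Lean and 0.585 for HFS against LF). Mean reads outside ribosomal RNA models were 10563454, 10347952, 12087575 and 12967862 in the same order (exact p = 0.025 and 0.655). To keep such abundant RNA from shifting every other gene, values were divided by a median-of-ratios factor (0.890 to 1.15) computed over genes with a mean of at least 1 and no 0. Left as deposited, the median log2 difference of all tested genes was 0.11 in GDM against Lean libraries and 0.11 in HFS against LF libraries, so all differences are relative to the bulk of genes. Of the 17322 models, those with a mean scaled value of at least 0.5 were tested. A RefSeq gene table of a later assembly matched 16410 models and was used for names only.

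Differences were tested in R 4.3.3 with limma 3.58.1 on log2(scaled value + 0.1), in 1 model of 4 group means over 12 libraries with 8 residual degrees of freedom and a variance trend. Fold changes are on that scale and understate the change of genes with low values. The 7 contrasts were GDM against Lean within each diet, HFS against LF within each kind of dam, both effects averaged over the other factor, and their interaction. P-values were two-sided, with Benjamini-Hochberg adjustment over all tested genes in a contrast and a threshold of 0.05. Errors of log2 differences are standard errors from limma, and errors of group values are SDs between libraries. Median standard errors were 0.16 for a contrast of 3 against 3, 0.12 for an averaged contrast and 0.23 for the interaction.

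Gene lists for cardiac pathways and cell types were fixed in advance: 48 were written and 46 had at least 5 tested members. In the sarcomere list the entry for titin (Ttn) was matched to Dbi, which is not a sarcomere gene. All values of that list include Dbi, and titin was not tested in it. Each was tested with camera in limma at a preset inter-gene correlation of 0.01, adjusted over the 46 lists, and again with camera's estimated correlation and with fry. None of the lists called in any of the 7 contrasts held with an estimated correlation. Scores of a list per library are the mean of log2(scaled value + 0.1) over its members, compared by exact exchange of labels within the strata of the other factor (400 assignments, smallest two-sided p 0.005).

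Genes were named by a rule. Per contrast it took up to 10 called genes of largest rise and 10 of largest fall with a mean of at least 1 and a symbol that is not an accession. Where fewer than 5 passed in a direction, those of smallest p were added up to 5 and are given as values. It also took the 4 members of smallest p in each called list, and 26 fixed cardiac genes. Members that passed when adjusted over the list alone, and smooth muscle genes, were named after their values were seen. Some genes that the rule takes are not reported here. Groups, model, filter, scaling, lists, naming rule and 27 of the 32 settings compared, main setting included, were chosen before the data were examined. The other 5 were chosen after: a mean of at least 5, no overlapping models, an adipocyte score as covariate, and count tests on the recovered reads with edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0. No replicate pair within a group agreed within counting noise (chi-square per degree of freedom 7.25 to 38.6).

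The procedure was tested on simulated values in which 200 genes changed. For GDM-LF against Lean-LF (12859 genes), 37.3, 68.7 and 83.1% of genes changed 1.5, 2 and 4 fold were called, with 10 of 135 calls false. For GDM against Lean (12858 genes) these shares were 56.7, 86.4 and 98.5%, with 10 of 169 calls false. For HFS against LF (12844 genes) they were 64.2, 83.1 and 95.4%, with 2 of 161 calls false. Without any change 0 genes were called, and a list shifted by 0.2 on the log2 scale was the only list called. The simulated genes varied independently of each other, so the simulation does not test how often lists of correlated genes are called.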

Results

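Heart transcripts were measured in young adult rats, with 3 libraries in each of the 4 groups. Groups differed in the dam's metabolic state and diet (Lean on LF or GDM on HFS) and in the diet after weaning (LF or HFS). Values are scaled, normalised reads of a gene model. Libraries held 9172734 to 14418970 reads outside ribosomal RNA models. The GDM libraries had a mean of 2072016 more of these than the Lean ones (exact p = 0.025). The first 5 principal components held 14.6, 12.1, 10.8, 9.67 and 9.24% of the variance. On the first, the 3 GDM-HFS libraries (21.1 to 38.0) and GDM-LF 3 (28.4) lay apart from the other 8 (-33.3 to 5.62), and Lean-HFS 2 had the highest score on the second (48.5).

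The first question was whether adult hearts differed between offspring of GDM and of Lean dams. Averaged over both diets, 7 genes were higher and 1 was lower in the 6 GDM than in the 6 Lean libraries, of 12980 tested, and each of the 8 separated the libraries completely. Kctd16, an auxiliary subunit of GABA-B receptors, averaged 8.16 ± 5.01 (SD, n = 6) in Lean and 90.8 ± 21.1 (SD, n = 6) in GDM hearts, a log2 difference of 3.62 ± 0.30 (limma, Benjamini-Hochberg adjusted p = 7.71e-05). Marcksl1, which binds actin and calmodulin, rose from 5.97 ± 1.06 to 30.6 ± 6.31 (log2 2.33 ± 0.17, limma adjusted p = 4.48e-05). Cyp4f18, a cytochrome P450 that hydroxylates lipids, rose from 3.22 ± 1.91 to 14.4 ± 1.87 (log2 2.35 ± 0.20, limma adjusted p = 7.71e-05). Rpl30, a protein of the large ribosomal subunit, fell from 189 ± 23.6 to 79.6 ± 19.8 (log2 -1.27 ± 0.14, limma adjusted p = 0.00128).

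The other 4 genes were also higher in GDM hearts. Serpina3n, a secreted inhibitor of serine proteases, had a mean of 1.16 ± 0.561 in Lean and 11.8 ± 7.67 in GDM libraries (log2 3.10 ± 0.44, limma adjusted p = 0.0152), from 2 to 10 recovered reads per Lean and 16 to 132 per GDM library. Vom2r17, of the vomeronasal receptor family, had 1 to 6 reads per Lean and 18 to 46 per GDM library (log2 2.74 ± 0.41, limma adjusted p = 0.0178). Tmem47, a membrane protein of cell junctions, rose from 139 ± 12.1 to 211 ± 9.38 (log2 0.60 ± 0.07, limma adjusted p = 0.00141), and Nxn, the redox protein nucleoredoxin, from 160 ± 17.3 to 225 ± 17.3 (log2 0.49 ± 0.07, limma adjusted p = 0.0178). The genes lie apart from each other. On Rnor_6.0, Kctd16 spans chr18 33445437 to 33727382, Marcksl1 chr1 84792039 to 84812668, Cyp4f18 chr16 19410810 to 19528935 and Rpl30 chr7 73213538 to 73216431. Serpina3n spans chr6 128073344 to 128080878, Vom2r17 chr1 65292448 to 65430211, Tmem47 chrX 48779110 to 48805644 and Nxn chr10 64412833 to 64550145. These are whole gene models, exons and introns together, and none of the 8 overlaps another tested model, although Rpl30, Serpina3n and Vom2r17 belong to families whose copies could share reads and are uncertain in that respect. The overlap check compares positions only, so it does not show whether Marcksl1, Cyp4f18 or the others have copies elsewhere that share reads.

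**Figure D1:**
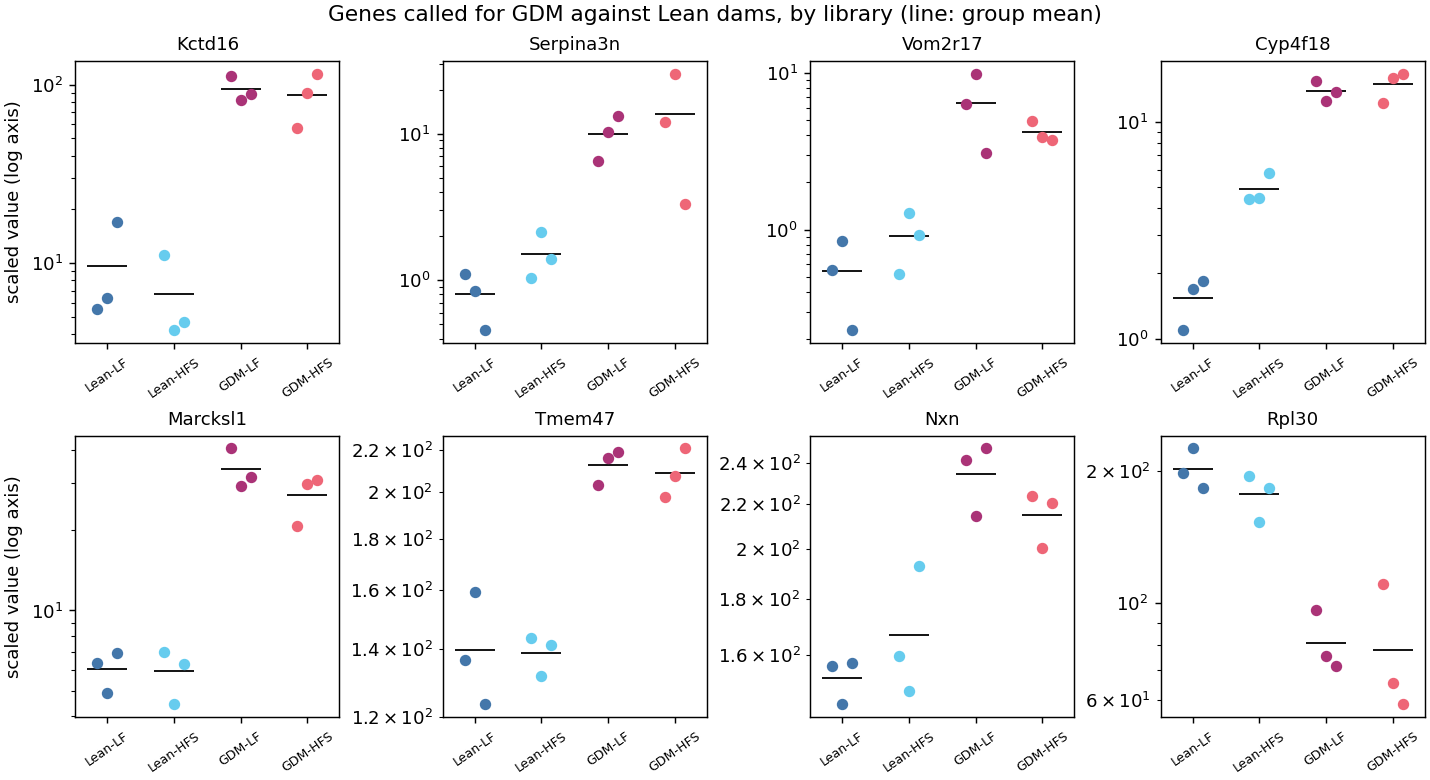
Scaled normalised reads (log axes) of the 8 genes called in GDM against Lean libraries, with 1 point per library and a line at each group's mean (n = 3). For every gene the 6 GDM libraries lie on one side of the 6 Lean libraries, as for Kctd16, with 4.23 to 17.0 in Lean and 57.3 to 115 in GDM hearts.

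At an unadjusted p under 0.05 there were 1459 genes, against 649 expected by chance, and edgeR on the recovered reads called 9 genes and DESeq2 152. Genes next in the ranking did not pass. They include Cited4, a transcriptional coregulator, at log2 -0.65 ± 0.11 (limma adjusted p = 0.0577), the leukocyte adaptor Lcp2 at -0.51 ± 0.09, Gpr155 at -0.45 ± 0.08 and the muscle acetylcholine receptor subunit Chrna1 at -2.21 ± 0.41 (limma adjusted p = 0.0706 for each of these 3). The call of Nxn ended without Lean-LF 2, Lean-HFS 1, GDM-LF 1 or 3, or GDM-HFS 1 or 3 (limma adjusted p = 0.0771, 0.0514, 0.0752, 0.0525, 0.0616 and 0.0524, with log2 differences of 0.47 to 0.48). That of Serpina3n ended without GDM-LF 2 or GDM-HFS 1 (0.0663 and 0.0554, at 3.08 and 3.04). That of Vom2r17 ended without any 1 of GDM-LF 1 and 2 and GDM-HFS 1, 2 and 3 (limma adjusted p = 0.0752, 0.0876, 0.0694, 0.0775 and 0.0524, at 2.55 to 2.77), and 20 genes were called without Lean-HFS 3. With the atrial score of each library as a covariate the calls of Nxn, Serpina3n and Vom2r17 ended (0.46 ± 0.09, 2.81 ± 0.53 and 2.78 ± 0.51, limma adjusted p = 0.169, 0.138 and 0.138). With the blood score those of Serpina3n and Vom2r17 ended (2.69 ± 0.48 and 2.66 ± 0.49, 0.0937 for both), and with the adipocyte score that of Nxn (0.48 ± 0.08, 0.0590).

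Among gene groups, 9 of the 46 lists were called in GDM against Lean hearts. Macrophage and monocyte markers were lower, with 18 of 19 members negative and a median log2 difference of -0.29 (camera adjusted p = 1.51e-05, and adjusted p = 0.859 with an estimated correlation). Adjusted over the list alone 3 fell and over all genes 0 did: Tyrobp, a signalling adaptor of myeloid cells, at -0.77 ± 0.17, the lysosomal protein Cd68 at -0.72 ± 0.21 and the surface marker Adgre1 at -0.47 ± 0.13. Cytosolic ribosomal proteins were lower in 46 of 61 members, with a median of -0.089 (camera adjusted p = 6.21e-06, and adjusted p = 0.665 with an estimated correlation). Adjusted over the list alone Rpl30 and Rps2 fell (-1.27 and -0.21 ± 0.05), and over all genes Rpl30 did. The sign of that median depends on scaling, since values as deposited gave 0.021, against 0.11 for all genes, while the list stayed below other genes (camera adjusted p = 0.00939). Erythroid transcripts were negative in 9 of 11 members, with a median of -0.32 (camera adjusted p = 0.00199, and adjusted p = 0.854 with an estimated correlation). Over the list alone 4 fell, among them Alas2, which starts haem synthesis in red cells, at -0.55 ± 0.15, and the overlapping alpha globin models Hba1 and Hba2, which share reads and are uncertain singly, at -0.67 and -0.65. Without overlapping models the median was -0.30 (camera adjusted p = 0.0541).

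Atrial markers were higher in 18 of 19 members, with a median of 0.63 (camera adjusted p = 3.53e-05, and adjusted p = 0.854 with an estimated correlation). Adjusted over the list alone 2 rose, the transcription factor Tbx5 at 0.88 ± 0.21 and the lipid transfer protein Stard10 at 0.96 ± 0.24, and over all genes 0. The median was 0.35 without Lean-HFS 2 and 0.36 without GDM-LF 3, and that of the macrophage markers -0.12 without Lean-HFS 2. The other 5 called lists each lost their call without 3 to 8 of the 12 libraries. Interferon response genes had a median of -0.15 (camera adjusted p = 0.00559) that reached -0.036 without GDM-LF 1 (adjusted p = 0.136), -0.068 without Lean-HFS 2 and -0.074 without Lean-LF 2, with the chemokine Cxcl9 falling over the list alone (-0.64). Antigen presentation genes (-0.13, adjusted p = 0.0378) reached -0.076 without GDM-LF 1 (adjusted p = 0.244) and -0.079 without Lean-HFS 2. Over that list alone RT1-T24-4, a class I gene whose model overlaps another and is uncertain, rose by 0.44 (limma adjusted p = 0.0706 over all genes), and there fell Cd74, the invariant chain of class II molecules, at -0.26, the peptide transporter Tap1 at -0.41 and the class I light chain B2m at -0.28. Ventricular markers (-0.16), nuclear complex I subunits (-0.051) and antioxidant genes (-0.078) had a camera adjusted p of 0.0454 each. The complex I median ranged from -0.0053 without Lean-HFS 1 to -0.13 without Lean-HFS 2, and the antioxidant median was -0.14 without Lean-HFS 1. As deposited, against 0.11 for all genes, these 2 medians were 0.059 and 0.032, with the calls lost. With an estimated correlation, adjusted p = 0.859 for the interferon and antigen presentation lists, 0.665 for ventricular markers, 0.894 for complex I and 0.854 for antioxidant genes.

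Single members of lists that were not called also passed over their list alone. Adra1b, an alpha-1 adrenergic receptor, was higher by 0.61 ± 0.10 (limma adjusted p = 0.0568 over all genes), the immediate early gene Fos by 1.23 ± 0.27, the potassium channel Kcnj5 by 0.70, the granulocyte enzyme Padi4 by 1.18 ± 0.27 and the imprinted zinc finger gene Peg3 by 0.41. The potassium channel subunit Kcne1 was lower (-1.90 ± 0.49), as were the pacemaker channel Hcn2 (-0.50), the chemokine Cxcl12 (-0.47 ± 0.10), the mast cell protease Cpa3 (-0.73) and the small heat shock proteins Hspb6 (-0.46) and Hspb8 (-0.21). Of the 26 fixed cardiac genes 0 were called by limma and 3 had an unadjusted p under 0.05: skeletal alpha actin Acta1 at -0.80 (-0.52 without Lean-HFS 2), the stretch-responsive gene Ankrd1 at -0.30 and Txnip, a thioredoxin inhibitor, at 0.50.

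**Figure D2:**
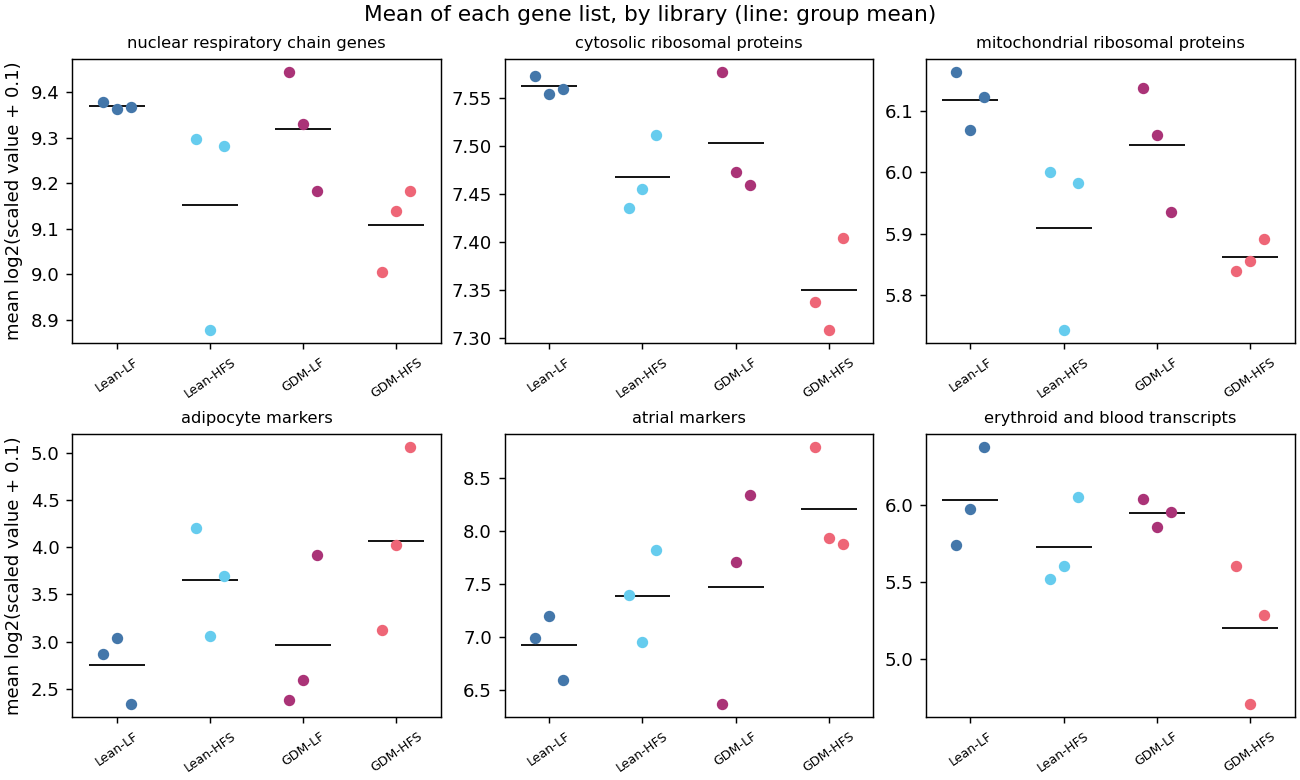
Mean log2(scaled value + 0.1) over the members of 6 gene lists in each of the 12 libraries, with a line at each group's mean (n = 3). Respiratory chain and ribosomal protein scores were lower on average in HFS libraries, with overlap, as for the respiratory score of GDM-LF 3 (9.18) and Lean-HFS 1 (9.30). Atrial scores ranged from 6.36 in GDM-LF 1 to 8.80 in GDM-HFS 1 and overlapped between groups.

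In offspring on the low fat diet, GDM-LF hearts had 3 genes higher and 1 lower than Lean-LF hearts (3 libraries each). Cyp4f18 was higher by 3.11 ± 0.28 (13.9 ± 1.53 against 1.55 ± 0.391, limma adjusted p = 0.000528), Marcksl1 by 2.47 ± 0.25 (limma adjusted p = 0.000792) and Kctd16 by 3.45 ± 0.42 (94.3 ± 15.5 against 9.65 ± 6.43, limma adjusted p = 0.00584). Rpl30 fell by 1.32 ± 0.20 (81.1 ± 13.3 against 202 ± 21.5, limma adjusted p = 0.0413). Below the threshold stood Tmem47 (0.61, limma adjusted p = 0.051), Nxn (0.62, 0.0783), the growth factor Fgf16 (-0.63, 0.269), Carhsp1 (-0.64, 0.269), the presynaptic protein Bsn (-1.02, 0.269) and Il18bp, which binds interleukin 18 (-0.77, 0.323). There were 647 genes at an unadjusted p under 0.05, about as many as the 649 expected, and edgeR called 4 and DESeq2 17. Over their lists alone Adra1b (0.55), Padi4 (1.34, or 0.89 without Lean-LF 2) and the uncertain RT1-T24-4 (0.50) rose, and the red cell enzyme Bpgm fell (-0.49).

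Of the lists, 2 were called between GDM-LF and Lean-LF hearts. Atrial markers were higher in 15 of 19 members (median 0.31) and cytosolic ribosomal proteins lower in 48 of 61 (median -0.058), both with a camera adjusted p of 0.0212 and an adjusted p = 0.932 with an estimated correlation. Over the list alone Rpl30 fell, as it did over all genes, and 0 atrial members passed. The atrial call ended without Lean-LF 3 (median 0.28) or GDM-LF 3 (0.047), its median was 0.48 without GDM-LF 1 and 0.20 without Lean-LF 2, and the ribosomal call without Lean-LF 1 (-0.042), GDM-LF 2 (-0.041) or GDM-LF 3 (-0.032), with a median of -0.088 without GDM-LF 1, while values as deposited ended both (medians 0.42 and 0.055, against 0.11 for all genes). Kctd16 had a limma adjusted p of 0.0577 without Lean-LF 1 (3.15) and 0.054 without GDM-LF 1 (3.32), and Rpl30 passed in 3 of the 12 fits that leave out 1 library (the highest adjusted p was 0.299, without GDM-LF 2, at -1.27). The Rpl30 call also ended with no filter, values as deposited, quantile normalization, robust variance or the atrial covariate (limma adjusted p = 0.0528, 0.0602, 0.0512, 0.0518 and 0.0911), with log2 differences of -1.32, -1.21, -1.32, -1.32 and -1.36.

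In offspring on the HFS diet, 2 genes were higher in GDM-HFS than in Lean-HFS hearts: Kctd16 by 3.78 ± 0.42 (87.4 ± 29.0 against 6.67 ± 3.86) and Marcksl1 by 2.19 ± 0.25 (both limma adjusted p = 0.00329). Cyp4f18 (1.59, 0.155), Tmem47 (0.59, 0.101) and Rpl30 (-1.23, 0.101) had the same sign as on the LF diet but did not pass by limma, and Kctd8, which like Kctd16 attaches to GABA-B receptors, stood at 1.52 ± 0.30 (limma adjusted p = 0.191). Tmem179 (-0.60) and Ddt, a relative of the cytokine MIF (-0.55), had a limma adjusted p of 0.191. At an unadjusted p under 0.05 there were 1251 genes, and edgeR called 2 and DESeq2 55. With the blood score as a covariate both calls ended (3.85 ± 0.54 and 2.14 ± 0.31, limma adjusted p = 0.0896), as did that of Marcksl1 when only these 2 groups were fitted (2.19 ± 0.27, 0.0665).

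The fixed list of smooth muscle and pericyte markers was not called between GDM-HFS and Lean-HFS hearts (median 0.028, camera adjusted p = 0.559), while fry's test for change in either direction gave an adjusted p of 0.0493. Adjusted over the list alone 4 of its 16 members rose, Cnn1 (calponin) by 2.10 ± 0.56, Acta2 (smooth muscle actin) by 1.17 ± 0.35, Myh11 (smooth muscle myosin) by 0.97 ± 0.25 and Tagln (transgelin) by 1.15 ± 0.36, and the pericyte gene Rgs5 fell by 0.39, while over all genes 0 passed. Cnn1 was at 19.7, 50.0 and 83.3 in GDM-HFS 1, 2 and 3, at 7.41 to 12.6 in Lean-HFS and at 5.46 to 20.4 in all 9 other libraries. For Acta2 GDM-HFS 1 (249) lay below Lean-HFS 3 (268). Over their lists alone Fos rose by 1.82 ± 0.38, Adra1b by 0.67, Kcnj5 by 0.97, Tbx5 by 1.02 and Stard10 by 1.26, whereas Kcne1 (-2.91), Hcn2 (-0.69), the mast cell gene Cpa3 (-0.91) and Myh2, a fast skeletal myosin (-1.67), fell, as did Hspb6 (-0.66), Hspb8 (-0.32) and Cd74 (-0.35). Kcnj5 was at 0.59 without Lean-HFS 2 and Myh2 at -1.07 without GDM-HFS 1.

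**Figure D3:**
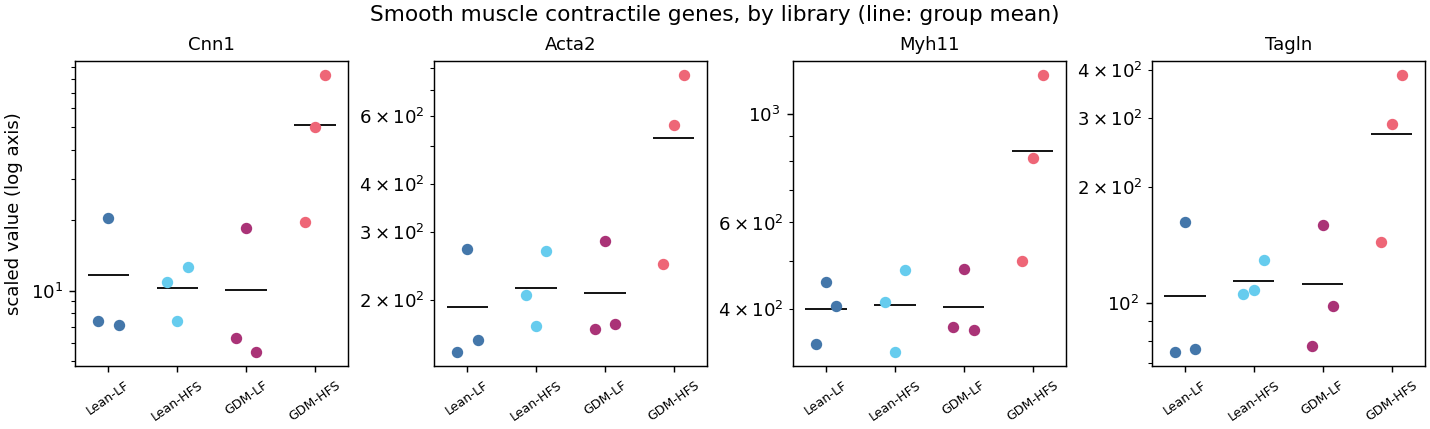
Scaled normalised reads (log axes) of 4 smooth muscle genes in each library, with a line at each group's mean (n = 3). GDM-HFS 2 and 3 lie above every other library for Cnn1, at 50.0 and 83.3, while GDM-HFS 1, at 19.7, lies above Lean-HFS (7.41 to 12.6) but within the range of the other libraries (5.46 to 20.4).

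There were 7 called lists between GDM-HFS and Lean-HFS hearts. Macrophage and monocyte markers were lower in 17 of 19 members (median -0.38, camera adjusted p = 1.03e-06), with Adgre1 falling over the list alone (-0.69). Endothelial markers were lower in 19 of 20 (median -0.21, camera adjusted p = 4.62e-05), with the vessel genes Tie1 (-0.36) and Egfl7 (-0.39) falling over the list alone. Cytosolic ribosomal proteins were lower in 45 of 61 (median -0.11, camera adjusted p = 6.66e-06), erythroid transcripts in 10 of 11 (median -0.51, camera adjusted p = 0.0024) and interferon genes in 25 of 33 (median -0.10, camera adjusted p = 0.0113). Atrial markers were higher in 18 of 19 (median 0.57, camera adjusted p = 0.000119) and calcium handling genes in 16 of 24 (median 0.14, camera adjusted p = 0.0101). With an estimated correlation, adjusted p = 0.649 for atrial markers, 0.854 for interferon genes and 0.644 for each of the other 5 lists.

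The macrophage median was -0.16 (camera adjusted p = 0.0507) without Lean-HFS 2, -0.59 without Lean-HFS 1 and -0.63 without Lean-HFS 3. The calcium call also ended without Lean-HFS 2 (median 0.049), the erythroid call without GDM-HFS 2 (-0.29) and the interferon call without either (-0.10 and -0.18). The interferon median was -0.26 without Lean-HFS 1, -0.22 without GDM-HFS 1 and -0.17 without GDM-HFS 3. The atrial median was 1.04 without Lean-HFS 3, the ribosomal median -0.046 without Lean-HFS 1 and -0.067 without GDM-HFS 2. With values as deposited the ribosomal and interferon medians were 0.0010 and 0.0076, against 0.11 for all genes, and the calls held (camera adjusted p = 0.0020 and 0.00262).

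The next question was what the HFS diet after weaning did. Averaged over both kinds of dam, nuclear transcripts of the respiratory chain were lower in the 6 HFS than in the 6 LF hearts, by small amounts in nearly every subunit. All 33 complex I subunits were negative (median -0.21, camera adjusted p = 2.32e-19, and adjusted p = 0.308 with an estimated correlation) and 37 of 38 subunits of complexes II to V (median -0.22, camera adjusted p = 1.51e-22, and adjusted p = 0.303 with an estimated correlation). Over each list alone 16 members fell, and over all genes 0 did. Among them were Uqcrb of complex III, at 404 ± 28.2 (SD, n = 6) in LF and 322 ± 20.1 in HFS hearts (-0.33 ± 0.06), the muscle isoform Cox6a2 of cytochrome oxidase (-0.48 ± 0.12), Cox8b (-0.41 ± 0.12) and the complex I subunits Ndufa6 (-0.32) and Ndufb9 (-0.29). Without Lean-HFS 2 the median of complexes II to V was -0.15 (camera adjusted p = 1.22e-16).

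Ribosomal protein transcripts were lower as well. Over tested genes the log2 differences of HFS against LF rose with gene span (Spearman rho 0.226). Whether span holds a part of the difference was tested for the respiratory chain and not for the other lists. Cytosolic ribosomal proteins were negative in 57 of 61 members (median -0.12, camera adjusted p = 3.8e-15), with Rpl34 falling over the list alone (-0.35), and mitochondrial ones in 36 of 38 (median -0.15, camera adjusted p = 4.27e-10), with 0 members passing. With an estimated correlation, adjusted p = 0.151 and 0.308. The cytosolic list was the only one in any contrast that fry called for a common direction (fry adjusted p = 0.0365). A score of 71 respiratory chain genes was lower by -0.21 in HFS libraries (exact two-sided p = 0.005 over exchanges within dams, the smallest possible), as was the cytosolic ribosomal score (-0.12, exact p = 0.005). Over all 46 lists 12 scores had an exact p under 0.05 and 0 an adjusted p under 0.05, the lowest Benjamini-Hochberg adjusted exact p being 0.0767. Because the exact p cannot go below 0.005, a few lists alone could not pass this adjustment.

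Transcripts for use of other fuels were also lower. Ketone body and branched-chain amino acid genes had a median of -0.18, with 17 of 20 negative (camera adjusted p = 5.81e-08, and adjusted p = 0.311 with an estimated correlation). Over the list alone 6 fell, among them the ketone enzyme Bdh1, from 195 ± 44.9 to 112 ± 41.7 (-0.86 ± 0.20), the transaminase Bcat2 (-0.40, or -0.26 without Lean-HFS 2) and the branched-chain genes Dbt (-0.33) and Ppm1k (-0.29). Glucose uptake and glycolysis genes had a median of -0.15, with 23 of 27 negative (camera adjusted p = 2.93e-06, and adjusted p = 0.303 with an estimated correlation), and over the list alone the insulin-responsive glucose transporter Slc2a4 (-0.46 ± 0.11), the muscle enolase Eno3 (-0.46) and hexokinase Hk2 (-0.23) fell. TCA cycle genes were negative in 21 of 21 (median -0.11, adjusted p = 0.524 with an estimated correlation). Without Lean-HFS 2 the glycolysis median was -0.10 and that of the TCA cycle -0.055.

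The sarcomere list, with Dbi in place of titin, was lower in 20 of 22 members (median -0.16, camera adjusted p = 3.48e-07, and adjusted p = 0.303 with an estimated correlation). Over the list alone the myosin light chain Myl2 (-0.36) and the chaperone Cryab (-0.31) fell. Ventricular markers (median -0.12, adjusted p = 0.153 with an estimated correlation) were lower too, with the transcription factor Irx4 falling over the list alone (-0.44) and a median of -0.21 without Lean-HFS 3. Autophagy and proteasome genes were also lower (median -0.070, and adjusted p = 0.311 with an estimated correlation), with Map1lc3a falling over the list alone (-0.25). With values as deposited, where the median of all genes was 0.11, the autophagy median was 0.028 and the call was lost (camera adjusted p = 0.0828). Erythroid transcripts were negative in 11 of 11 (median -0.36, camera adjusted p = 6.11e-06), and -0.22 without GDM-HFS 2. Adipocyte markers were higher in 15 of 16 (median 0.49, camera adjusted p = 6.48e-06), with the lipid droplet coat protein Plin1 (2.12 ± 0.69), the glyceroneogenic enzyme Pck1 (2.13 ± 0.69) and the lipase Lipe (0.29) rising over the list alone. Both lists had an adjusted p = 0.303 with an estimated correlation, and the adipocyte median was 0.32 without Lean-LF 3 and also without GDM-HFS 3. Immediate early genes were higher (median 0.21, camera adjusted p = 0.000808, and adjusted p = 0.493 with an estimated correlation), with Egr3 (1.78 ± 0.49) and the RNA-binding protein Zfp36 (0.54) rising over the list alone. Their median was 0.12 without Lean-LF 3, 0.11 without GDM-LF 1, 0.13 without GDM-HFS 2 and 0.12 without GDM-HFS 3. With the blood score as a covariate the camera test of immediate early genes turned in direction. Atrial markers were higher by a median of 0.28 (adjusted p = 0.524 with an estimated correlation), and by 0.18 without GDM-LF 1 and 0.13 without GDM-HFS 1.

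The 14 lists above, of 24 called, held when each library was left out in turn, and the other 10 did not. PPAR targets had a median of 0.13 (camera adjusted p = 0.00396, but 0.212 without Lean-HFS 1, where the median was 0.084, and 0.174 without GDM-LF 3, and adjusted p = 0.537 with an estimated correlation). Lipid droplet genes had a median of 0.14 (camera adjusted p = 0.0109, but 0.268 without Lean-HFS 1, where the median was 0.074, 0.0883 without GDM-LF 3 and 0.0661 without GDM-HFS 3, and adjusted p = 0.524 with an estimated correlation). Over that list alone Gpihbp1, which carries lipoprotein lipase to capillaries, rose from 33.0 ± 16.6 to 70.6 ± 13.3 (1.22 ± 0.27). Extracellular matrix genes had a median of 0.089, which was -0.038 without Lean-HFS 2, 0.044 without GDM-LF 1, 0.13 without GDM-LF 3, 0.17 without Lean-HFS 1 and 0.19 without Lean-HFS 3 (adjusted p = 0.722 with an estimated correlation). Mesothelial markers stood at 0.73, glucocorticoid targets at 0.27 and imprinted genes at 0.15, with Dlk1, at a mean of 0.149 in LF and 1.30 in HFS hearts, rising (2.85 ± 0.77) and the zinc finger gene Zim1 falling (-0.57 ± 0.17) over the list alone. With the blood score as a covariate Zim1 was at -0.091, and Dlk1 was at 1.70 with the adipocyte score. Interferon genes stood at -0.095, sterol synthesis genes at -0.081, with the desaturase Scd2 falling over the list alone (-0.54), heat shock proteins at -0.076 and cell cycle genes at -0.11. As deposited, against 0.11 for all genes, the medians of the interferon, sterol and heat shock lists were 0.0038, 0.017 and 0.022 (camera adjusted p = 4.53e-05, 0.0224 and 0.0525). These last 7 lists lost their calls without 1 to 5 libraries, and the highest camera adjusted p was 0.28 for mesothelial markers (without GDM-HFS 1), 0.459 for glucocorticoid targets (without GDM-LF 3), 0.292 for imprinted genes (without Lean-HFS 3), 0.0802 for interferon genes (without GDM-LF 2), 0.116 for sterol genes (without GDM-HFS 1), 0.13 for heat shock proteins (without GDM-LF 2) and 0.127 for cell cycle genes (without GDM-LF 3). The mesothelial median was 0.44 without GDM-HFS 1. The imprinted one was 0.078 without GDM-HFS 1, 0.080 without Lean-HFS 3 and 0.086 without Lean-LF 2. The sterol one was -0.040 without Lean-HFS 2 and -0.054 without GDM-LF 1. That of interferon genes was -0.025 without GDM-LF 2, -0.046 without Lean-LF 2 and -0.15 without GDM-LF 1. For heat shock proteins the median was -0.033 without GDM-LF 2, -0.12 without Lean-LF 2 and -0.11 without GDM-LF 3. That of cell cycle genes was -0.064 without GDM-HFS 3, -0.067 without Lean-HFS 3, -0.17 without GDM-HFS 1 and -0.19 without GDM-LF 1. With an estimated correlation, adjusted p = 0.579 for glucocorticoid targets, 0.311 for sterol genes, 0.537 for heat shock proteins and 0.524 for the other 4.

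**Figure D4:**
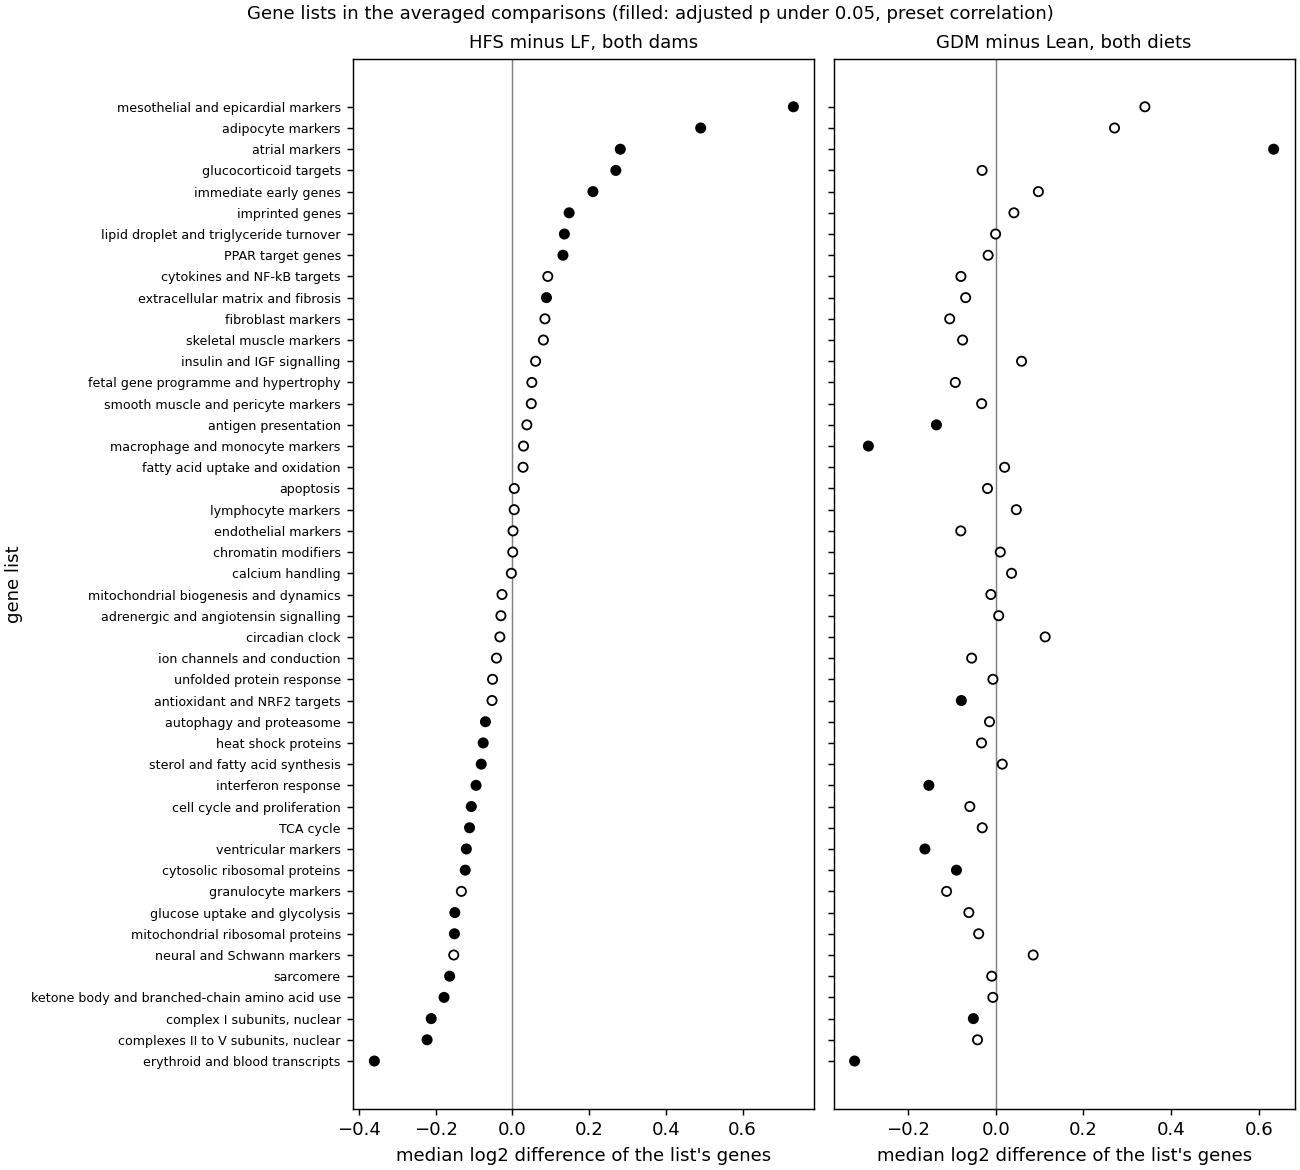
Median log2 difference over the members of each of the 46 lists in HFS against LF and in GDM against Lean libraries (6 against 6), with filled points where the camera adjusted p was under 0.05 at the preset correlation. Respiratory chain lists lie near -0.21 in the HFS contrast, and none of the filled points held with an estimated correlation.

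Single genes were not called by limma in HFS against LF hearts (0 genes, lowest adjusted p = 0.108) nor by edgeR (0), and DESeq2 called 31, with 1028 genes at an unadjusted p under 0.05. Nearest to the threshold was Slc25a29, a mitochondrial carrier of basic amino acids, at 38.8 ± 4.02 in LF and 24.1 ± 3.24 in HFS hearts (-0.69 ± 0.10, limma adjusted p = 0.108). The RNA-editing enzyme Adarb1 stood at 0.38 ± 0.06 (limma adjusted p = 0.262). The activin receptor Acvr1b (0.36), Tmcc3 (0.27), the transfer RNA methyltransferase Trmt10b (0.66), the G-protein regulator Rgs4 (-0.41), the ATP-sensitive potassium channel Kcnj11 (-0.31) and the exosome subunit Exosc4 (-0.57) had a limma adjusted p of 0.389. Of the smooth muscle and pericyte list, which was not called (camera adjusted p = 0.269), Cnn1 (1.15), Acta2 (0.71), Myh11 (0.50), Tagln (0.73) and Lmod1 (0.76) rose and Kcnj8 fell (-0.26) over the list alone. With the adipocyte score as a covariate Cnn1 was at 0.66 and Myh11 at 0.19. Within the offspring of Lean dams these genes did not separate the diets, and no member passed over the list alone. Cnn1 was at 7.14 to 20.4 in Lean-LF and 7.41 to 12.6 in Lean-HFS hearts, and Myh11 at 338 to 453 and 326 to 481. Over other lists that were not called the endothelin receptor Ednrb rose (0.29) and the glutathione transferase Gstm2 (-0.39) and RT1-T24-4 (-0.34) fell. Of the 26 fixed genes 0 were called and 4 had an unadjusted p under 0.05, among them Slc2a4, the natriuretic peptide Nppa (1.54 ± 0.61, or 0.94 without GDM-LF 1) and Angptl4, an inhibitor of lipoprotein lipase (1.06).

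Within the offspring of Lean dams, limma called 0 genes between Lean-HFS and Lean-LF hearts (lowest adjusted p = 0.802, 676 genes at an unadjusted p under 0.05), and edgeR and DESeq2 also called 0. The respiratory chain was lower, with 33 of 33 complex I subunits (median -0.21, camera adjusted p = 4.38e-14) and 37 of 38 subunits of complexes II to V negative (median -0.20, camera adjusted p = 2.54e-14), and Uqcrb fell over its list alone (-0.35 ± 0.09). Lower too were ketone and branched-chain genes (18 of 20, median -0.24), mitochondrial ribosomal proteins (35 of 38, -0.18), cytosolic ones (52 of 61, -0.091), sarcomere genes (21 of 22, -0.17) and glycolysis genes (20 of 27, -0.13). With values as deposited the cytosolic median was 0.011, against 0.11 for all genes, and the list was still called lower (camera adjusted p = 0.00552). Adipocyte markers were higher in 14 of 16 (median 0.45), and Gpihbp1 rose over its list alone (1.42 ± 0.38). With an estimated correlation, adjusted p = 0.433 for the complex I, complexes II to V, ketone, glycolysis and adipocyte lists, and the lowest for any list was that value. Cyp4f18 was at 1.55 ± 0.391 in Lean-LF and 4.89 ± 0.808 in Lean-HFS hearts (1.61 ± 0.28, limma adjusted p = 0.802), and Fxyd7 (1.64), Stard6 (1.19), Pibf1 (0.43), Cep78 (-0.91) and Il18bp (-0.77) were also not called.

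Of the 21 lists called there, 9 kept the call in each of the 12 fits without 1 library and 12 did not. Lean-HFS 2 carried much of the size: without it the medians were -0.083 for complex I, -0.064 for complexes II to V, -0.075 for mitochondrial ribosomal proteins, -0.064 for glycolysis and -0.14 for ketone genes. Without it extracellular matrix and macrophage genes turned from 0.16 to -0.077 and from 0.18 to -0.22, while without Lean-HFS 3 these were at 0.29 and 0.34. The macrophage median was also 0.34 without Lean-HFS 1 and 0.091 without Lean-LF 3. The adipocyte call ended without Lean-LF 3 (median 0.25) or Lean-HFS 1 (0.39), with a median of 0.27 without Lean-LF 1, and without Lean-HFS 1 the medians were -0.31 for complexes II to V and -0.30 for the sarcomere. Without Lean-LF 3, limma called 3 genes and camera 11 lists.

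Within the offspring of GDM dams, limma again called 0 genes between GDM-HFS and GDM-LF hearts (lowest adjusted p = 0.129, 723 at an unadjusted p under 0.05), edgeR 0 and DESeq2 6. Respiratory chain transcripts were lower, with 33 of 33 complex I subunits (median -0.19) and 37 of 38 of complexes II to V negative (median -0.20, camera adjusted p = 2.3e-15), both with an adjusted p = 0.532 with an estimated correlation. Over the list alone Uqcrb (-0.31) and Cox6a2 (-0.64 ± 0.17) fell with 2 ATP synthase subunits. Cytosolic ribosomal proteins were negative in 57 of 61 (median -0.14, camera adjusted p = 1.48e-13, and adjusted p = 0.2 with an estimated correlation), and the chaperone Cryab fell over its list alone (-0.45 ± 0.10). Erythroid transcripts had a median of -0.59 and cell cycle genes of -0.30 (25 of 30 negative), with adjusted p = 0.484 and 0.532 with an estimated correlation. Immediate early genes were positive in 22 of 27 (median 0.18, and adjusted p = 0.532 with an estimated correlation).

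Of the smooth muscle and pericyte list, over the list alone Cnn1 (2.32 ± 0.56), Acta2 (1.23 ± 0.35), Myh11 (0.98 ± 0.25), Tagln (1.24 ± 0.36) and Lmod1 (0.94 ± 0.31, or 0.59 without GDM-HFS 3) rose in GDM-HFS against GDM-LF hearts and the pericyte channel Kcnj8 fell by 0.39, while the list as a whole was not called (camera adjusted p = 0.0817). Over the endothelial list alone Tie1 (-0.33) and the water channel Aqp1 (-0.57) fell. Nearest to a call was Tmem179, at -0.76 ± 0.11 (limma adjusted p = 0.129). Slc25a29 (-0.68), Rgs4 (-0.54), Tp53i11 (-0.52), Ddt (-0.47), tropomyosin Tpm2 (0.89), Rgs7 (0.89), Adarb1 (0.45) and Kank1 (0.33) had a limma adjusted p of 0.761.

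Of the 23 lists called in GDM-HFS against GDM-LF hearts, 7 kept the call in each of the 12 fits without 1 library and 16 did not. Without GDM-HFS 1, 15 lists were called, and the complex I and mitochondrial ribosomal medians were -0.13 and -0.080; the erythroid median was -0.30 without GDM-HFS 2 and the cell cycle median -0.19 without GDM-HFS 3. The immediate early median was 0.34 without GDM-HFS 1 and 0.28 without GDM-LF 2, and the mitochondrial ribosomal median -0.20 without GDM-HFS 3. With the blood score as a covariate the camera test of immediate early genes turned in direction here too.

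Last, the interaction asked whether the maternal effect differed between diets. Limma called 0 genes (lowest adjusted p = 0.999) and edgeR and DESeq2 0. There were 391 genes with an unadjusted p under 0.05, fewer than the 649 expected by chance. Cyp4f18 came near the top, with a difference between GDM and Lean of 3.11 on LF and 1.59 on HFS (-1.52 ± 0.40), where Lean-LF hearts had 1.55 and Lean-HFS hearts 4.89, and Tmem179 stood at -0.76 ± 0.16. The Rd3l (0.97), Pola2 (-1.10) and Tril (-0.51) values had the same limma adjusted p of 0.999. Of the lists 8 were called, led by endothelial markers, where all 20 members were negative (median -0.23, camera adjusted p = 2.45e-07, or -0.40 without GDM-LF 3), and macrophage markers, with 18 of 19 negative (median -0.32, camera adjusted p = 0.00793, or -0.039 without Lean-HFS 2 and -0.21 without GDM-HFS 3, where the call ended). All 8 had an adjusted p = 0.96 with an estimated correlation, and 0 members passed over their list alone.

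Across the 12980 tested genes, which are not independent replicates, log2 differences of GDM against Lean on the LF and on the HFS diet, which share no library, had a Pearson r of 0.214 (Spearman rho 0.238, jackknife error 0.0922 over libraries, and r = 0.123 without GDM-LF 3), and 60.8% had the same sign. At an unadjusted p under 0.05 in both, 64 genes were higher in both against 16.2 for independent lists, 80 were lower in both against 14.9, and 4 were opposite. The maternal and the diet effects had an r of 0.134 (rho 0.142, jackknife error 0.316), with 56.2% of the same sign, so their similarity was smaller than its error. There 73 genes were higher in both against 30.0 for independent lists, 72 lower in both against 27.8 and 30 opposite.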

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

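The tests of tissue share for the maternal genes, of the share of cardiac muscle and of a maternal effect on atrial markers, the adipocyte covariate and the search for genes with opposite directions were chosen only after the results were seen.

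By the interaction test at camera's preset correlation, 8 gene lists were called for a different maternal effect between diets. Of 100 splits of the libraries 90 called as many, so chance cannot be excluded for this count. Those splits exchanged dam labels within diets and can hold a part of the maternal difference, so they do not measure chance alone. Endothelial markers had a median difference of maternal effects of -0.23 (camera adjusted p = 2.45e-07) and macrophage and monocyte markers of -0.32 (0.00793), so both stood lower in GDM-HFS hearts than the separate effects add up to. Neural and Schwann markers had a median of 0.64 (0.0149), cell cycle genes of -0.23 (0.0149), fatty acid oxidation genes of 0.14 (0.0212), calcium handling genes of 0.18 (0.0212), ion channel genes of 0.21 (0.0427) and ketone and branched-chain genes of 0.15 (0.0427). All 8 had an adjusted p = 0.96 with an estimated correlation. The endothelial call alone held in each of the 12 fits without 1 library. Its median was -0.40 without GDM-LF 3. The macrophage call ended without Lean-HFS 2 (median -0.039) or GDM-HFS 3 (-0.21), and the other 6 ended without 4 to 8 of the libraries. The neural median was 0.42 without GDM-HFS 1. That of cell cycle genes was -0.40 without GDM-LF 1, -0.49 without GDM-HFS 1 and -0.15 without GDM-HFS 3. Calcium handling genes were at 0.066 without Lean-HFS 2 and 0.12 without GDM-LF 2, ion channel genes at 0.11 without Lean-LF 3 and ketone genes at -0.033 without Lean-HFS 2. Fatty acid genes were at -0.037 without Lean-HFS 2, 0.021 without GDM-LF 3 and 0.075 without GDM-HFS 2. They were at 0.22 without Lean-LF 3 or Lean-HFS 3, 0.23 without GDM-HFS 1, 0.24 without GDM-LF 1 and 0.29 without Lean-HFS 1.

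Some single genes had differences of opposite sign with no overlap between the libraries of the groups compared, without passing the interaction test (limma adjusted p = 0.999 for each). Ephx2, the soluble epoxide hydrolase, ranged from 82.0 to 152 in Lean-LF and 57.6 to 70.1 in Lean-HFS hearts but from 56.8 to 99.2 in GDM-LF and 103 to 114 in GDM-HFS hearts (log2 difference of differences 1.24). The growth factor Fgf16 (0.53) and the potassium channel Kcna4 (1.01) likewise were lower in Lean-HFS than in Lean-LF libraries and higher in GDM-HFS than in GDM-LF libraries, Fgf16 at 60.9 to 72.1 in Lean-LF, 45.5 to 57.7 in Lean-HFS, 40.7 to 44.1 in GDM-LF and 44.4 to 50.3 in GDM-HFS hearts. Ppp1r14a, an inhibitor of myosin phosphatase, was lower with GDM on LF (9.64 to 12.3 against 14.4 to 15.7) and higher on HFS (15.7 to 21.2 against 9.52 to 15.4), a difference of 1.20. Zfyve21 (0.56), whose model overlaps Ppp1r13b and is uncertain, had the same directions, and the acrosomal gene Acrbp the opposite ones (-2.53).

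The maternal genes were the first pattern weighed. Of the genes tested, 7 left a gap of at least 0.5 on the log2 scale between all Lean and all GDM libraries. Of the 462 splits into 6 and 6, only 1, the real one, reached that count (highest other 5). Chance separation is thus argued against for this count where libraries vary independently, but litters are unknown, so it cannot be excluded. The count does not stand for the 8 called genes. Smaller gaps lay between the nearest Lean and GDM values of Nxn (193 and 201), Tmem47 (159 and 198) and Rpl30 (153 and 110), so it does not cover them. A different share of atrial tissue, blood or fat is argued against as the whole cause. Of the 8 called genes, 5 stayed called with the atrial score as a covariate, 6 with the blood score and 7 with the adipocyte score. With the atrial score Serpina3n moved from 3.10 ± 0.44 to 2.81 ± 0.53, Vom2r17 from 2.74 ± 0.41 to 2.78 ± 0.51 and Nxn from 0.49 ± 0.07 to 0.46 ± 0.09. With the blood score Serpina3n was at 2.69 ± 0.48 and Vom2r17 at 2.66 ± 0.49, and with the adipocyte score Nxn was at 0.48 ± 0.08. Tissue share may thus hold a part of the Serpina3n difference. Macrophage and ventricular scores, with an exact two-sided p of 0.005 and 0.02 between the dams, were not used as covariates. A candidate explanation that passed its test is different parentage, with inherited variants acting on neighbouring genes. Of the 100 genes of smallest p for GDM against Lean, 26 lay within 1 Mb of another, against a median of 14 in 10000 random sets (permutation p = 0.0139), while 17 of those for the randomly assigned diet did (permutation p = 0.346). Maternal diabetes stays open beside it, untested, because the labels name neither dams nor litters. It also cannot be told apart from the HFS diet that the GDM dams ate from before mating until the end of lactation.

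The lower nuclear respiratory chain transcripts of HFS hearts were the second, with a median of -0.22 over 71 genes. More fat in HFS samples is argued against, since the median was -0.28 with the adipocyte score as a covariate. A bias by gene span, introns included, is argued against as the whole cause. Of 10000 lists matched on gene span and level, 0 had a median as low (their median was -0.078). Log2 differences nevertheless rose with span (Spearman rho 0.226 across genes, which are not independent), so part of the size may go with span. Transcript length without introns was not matched, so a bias by that length was not tested and stays open. A lower share of cardiac muscle cells cannot be told apart from an effect of the diet, as 1 of 6 lists of other cell types lay below 0 (neural markers, -0.15), the others lay between 0.0019 and 0.085, and the sarcomere list, Dbi included, was at -0.16. The diet itself stays open, and the median was -0.15 without Lean-HFS 2.

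The third was the wide spread of atrial markers, with Myl7 from 54.9 to 3799 and the natriuretic peptide Nppa from 355 to 10910, lowest in GDM-LF 1 and highest in GDM-HFS 1. A varying share of atrial tissue in the sampled heart is a candidate explanation that cannot be told apart from regulation within the tissue. The deviations of the 19 tested markers had a median pairwise Pearson correlation of 0.482, between the bounds of 0.2 and 0.5 set beforehand, and 81 of 171 pairs exceeded 0.5. An effect of the maternal group stays open as well, since the score differed by 0.68 between GDM and Lean libraries with an exact two-sided p = 0.09 and 6 libraries an arm. All 19 markers passed the filter in these whole hearts, which hold atria and ventricles.

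Other splits of the same libraries set the scale for the counts. For the 8 genes of GDM against Lean, 1 of 100 splits, the real one, had as many (highest other 7). Chance is thus argued against for libraries that vary independently, but another split came close and litters are unknown, so it cannot be excluded. For the 9 lists of that contrast 80 of 100 splits had as many (highest other 28), for the 24 lists of HFS against LF 7 of 100 did (highest other 28) and for the 8 lists of the interaction 90 of 100 did (highest other 29), so chance cannot be excluded for these counts. With 0 genes called in HFS against LF and in the interaction, all 100 of the 100 splits had as many by definition, so these counts decide nothing. Their highest other values were 104 and 8. The interaction split with 8 genes set all Lean against all GDM libraries, so it is the maternal contrast itself and not chance. Splits for the interaction exchanged dam labels within diets, so they can hold a part of the maternal difference and do not measure chance alone. The split with 104 genes set Lean-LF 3, Lean-HFS 2 and 3, GDM-LF 3 and GDM-HFS 1 and 2 against the rest, and no cause was tested for it. At camera's preset correlation the median of the other splits was 14 lists for GDM against Lean, 16 for HFS against LF and 14 for the interaction.

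Contrasts of 3 against 3 libraries allow 10 splits, too few for a share under 0.05. Genes numbered 4 in GDM-LF against Lean-LF (1 of 10 splits had as many, highest other 2), 2 in GDM-HFS against Lean-HFS (1 of 10, highest other 1), 0 in Lean-HFS against Lean-LF (10 of 10, highest other 0) and 0 in GDM-HFS against GDM-LF (10 of 10, highest other 1). Lists in the same order numbered 2 (10 of 10, highest other 19), 7 (10 of 10, highest other 25), 21 (1 of 10, highest other 19) and 23 (2 of 10, highest other 24).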

How the results depend on the processing

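The fits with edgeR, DESeq2, a mean of at least 5, no overlapping models and an adipocyte covariate, and the tests that rest on them, were chosen only after the data were seen. Each count of genes and lists was recomputed under 31 alternatives where these applied. The cause of a change was not tested unless stated. Sex as a covariate was not run, because Y-linked reads were present in all 12 libraries. Depth limits genes of few reads, such as Serpina3n and Vom2r17 with 1 to 10 reads in Lean libraries. Without 1 library an arm of 3 against 3 keeps 2, and the pooled spread assumes that they vary like the other groups.

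Of single genes named in the text, 4681 values under other settings kept their direction and side of the threshold, 95 passed it anew, 41 no longer passed and 0 changed sign. Of called lists 2265 values were kept, 500 lost the call and 14 changed the direction of the camera test.

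For GDM against Lean, 8 genes became 13 with values as deposited, 24 with library weights, 152 with DESeq2 and 6 to 20 with 1 library left out. For GDM-LF against Lean-LF, 4 genes became 7 with library weights, 17 with DESeq2 and 2 to 6 with 1 library left out. For GDM-HFS against Lean-HFS, 2 became 0 with the blood score as a covariate, 1 with only these 2 groups fitted, 55 with DESeq2 and 2 to 4 with 1 library left out. For GDM-HFS against GDM-LF, 0 became 1 with library weights, 1 with only these groups fitted, 6 with DESeq2 and 0 to 1 with 1 library left out. Lean-HFS against Lean-LF kept 0 except for 0 to 3 with 1 library left out, HFS against LF had 31 with DESeq2 and 0 in each fit with 1 library left out, and the interaction had 0 throughout.

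Called lists depended on the correlation. The estimated correlation left 0 lists in each of the 7 contrasts, and fry left 1 in HFS against LF and 0 in the other 6. For change in either direction fry called 2 lists in GDM-HFS against Lean-HFS, 4 in GDM against Lean, 1 in HFS against LF and 0 in the other 4 contrasts. With 1 library left out the counts ranged from 2 to 15 for GDM-LF against Lean-LF (main 2), 6 to 15 for GDM-HFS against Lean-HFS (7), 11 to 24 for Lean-HFS against Lean-LF (21), 15 to 25 for GDM-HFS against GDM-LF (23), 6 to 14 for GDM against Lean (9), 20 to 25 for HFS against LF (24) and 3 to 13 for the interaction (8). For GDM-LF against Lean-LF, 4 lists were called with the atrial covariate, 5 without overlapping models, 6 with the adipocyte covariate and 13 with only these groups fitted. For GDM-HFS against Lean-HFS there were 13 with values as deposited and 12 with library weights or the atrial covariate. Scaling moved the balance of higher to lower calls in some contrasts. Genes of GDM-LF against Lean-LF went from 3 higher and 1 lower to 3 and 0 both as deposited and after quantile normalization, and lists there from 1 and 1 to 0 and 3 as deposited. Lists of GDM against Lean went from 1 higher and 8 lower to 3 and 9 as deposited and 2 and 7 after quantile normalization, which also moved Lean-HFS against Lean-LF from 6 and 15 to 9 and 14, GDM-HFS against GDM-LF from 8 and 15 to 10 and 12 and the interaction from 5 and 3 to 3 and 4. EdgeR's camera left 5 lists for GDM against Lean, the blood covariate 15 for HFS against LF and no filter 4 for the interaction.

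Some lists turned in the camera test with a covariate. The atrial and blood scores are the means of the atrial and erythroid lists themselves. Loss of those lists' differences under their own score was thus fixed in advance and tells nothing about them. With the atrial score the atrial markers of GDM-LF against Lean-LF turned in the camera test (median 0.021). With the blood score the same happened to erythroid transcripts (0.18) and immediate early genes (0.015) of GDM-HFS against GDM-LF, and in HFS against LF to erythroid transcripts (-0.041), extracellular matrix genes (0.014) and immediate early genes (-0.031).

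Leaving out 1 library turned other lists. In Lean-HFS against Lean-LF, PPAR targets ranged from -0.035 (without Lean-HFS 1) to 0.24, and without Lean-HFS 2 extracellular matrix genes reached -0.077 (highest 0.29) and macrophage markers -0.22 (highest 0.34). In GDM-HFS against GDM-LF, fatty acid genes ranged from -0.011 (without GDM-LF 3) to 0.23 and TCA cycle genes from -0.16 to 0.012 (without GDM-HFS 1). Without Lean-HFS 2 extracellular matrix genes of HFS against LF were at -0.038 (highest 0.19), and in the interaction fatty acid genes were at -0.037 (highest 0.29) and ketone genes at -0.033 (highest 0.21).

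The similarity of the maternal effects between diets (r = 0.214) was 0.309 with a pseudocount of 1, 0.336 and 0.387 with a mean of at least 2 and 5, 0.321 with the atrial covariate and 0.123 to 0.241 with 1 library left out. That of maternal and diet effects (0.134) was 0.454 with the blood covariate and -0.019 to 0.232 with 1 library left out.

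The replicate numbers were not taken as pairs, since 1 of 18 pairs of the same number had deviations correlated above 0.1 (mean r 0.0036, against -0.0018 for other pairs, exact one-sided p = 0.356). In 8 of 12 libraries the highest correlation with any library of another group was with one of their own number (exact one-sided p = 0.0972 over 216 assignments of the numbers), and 0 of 12 correlated best with it in every other group. Agtr1b was low in the library numbered 2 of every group. With the replicate block 1 gene was called in GDM-HFS against GDM-LF (Tmem179, limma adjusted p = 0.0280), 6 lists in GDM-LF against Lean-LF and 10 genes in GDM against Lean. Nxn in GDM-LF against Lean-LF (0.0296), Rpl30 in GDM-HFS against Lean-HFS (0.0342) and Chrna1 in GDM against Lean (0.0325) passed, and the mesothelial list of GDM-HFS against GDM-LF lost its call (0.0540). No other call named in the text changed with it.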

Other observations

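The test on animal numbers, the search for genes with separate levels and the choice of libraries and genes described here came only after the data were seen.

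Library Lean-HFS 2 held the highest or lowest value of the 12 for 3672 of 10895 genes with a mean of at least 5, against 1298 to 2519 in each other library, and lay outside the range of the others by at least 1 on the log2 scale for 53 (2 to 21 in the others). The genes given next were picked after their values were seen. The alpha myosin heavy chain Myh6 was at 28847 there and at 62300 to 102097 in the other 11 libraries, while the natriuretic peptide Nppb was at 641 (207 to 379 elsewhere), the matrix protein Postn at 369 (15.7 to 97.0) and the matrix protein Thbs4 at 157 (3.39 to 38.9). Highest there as well were the skeletal alpha actin Acta1 at 5767 (584 to 2508), the stretch-responsive gene Ankrd1 at 13880 (6941 to 11652), the matrix-associated protein Ctgf at 783 (138 to 460) and the growth factor Tgfb2 at 272 (75.4 to 138), and lowest were the calcium pump Atp2a2 at 26305 (36873 to 43128) and the sodium channel subunit Scn4b at 362 (560 to 900). Within the range of the other libraries lay Nppa at 4937 (355 to 10910) and the beta myosin heavy chain Myh7 at 31731 (12063 to 38195). Its macrophage score was also the highest of the 12, at 5.75 on the log2 scale. The fetal gene programme as a list was called in no contrast (median 0.051 in HFS against LF, camera adjusted p = 0.251, and -0.092 in GDM against Lean, adjusted p = 0.239), nor were the lists for mitochondrial biogenesis, adrenergic signalling, fibroblasts, lymphocytes, granulocytes, skeletal muscle, cytokines, the circadian clock, the unfolded protein response, apoptosis and chromatin modifiers. The smooth muscle list was not called either.

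Transcripts of fat cells varied over a wide range. The hormone Adipoq lay between 0.43 in GDM-LF 2 and 27.6 in GDM-HFS 3, and Plin1 between 0.42 and 45.9. Ucp1, the uncoupling protein of brown fat, had no reads in 7 libraries and reached 37.8 in GDM-HFS 3, 11.4 in Lean-HFS 1 and 5.59 in Lean-HFS 3. Scores of the 13 cell type lists were compared by exact exchange of labels within strata. The macrophage score was lower in GDM libraries by -0.33 (exact two-sided p = 0.005, adjusted p = 0.065). In HFS against LF the erythroid score was -0.53 (exact p = 0.02, adjusted p = 0.13) and the adipocyte score 1.00 (exact p = 0.03, adjusted p = 0.13). The ventricular score was -0.17 for both factors (exact p = 0.02, adjusted p = 0.13). None passed after Benjamini-Hochberg adjustment. The exact p cannot go below 0.005, and 1 list alone at that value among 13 has an adjusted p of 0.065. The macrophage score thus could not have passed alone.

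A few genes took separate levels that followed neither dam nor diet completely. Of genes with a mean of at least 5, 5 split the libraries by a gap of at least 2 on the log2 scale with 3 or more libraries on each side. Fam111a (Rnor_6.0 chr1 229003961 to 229019527), which encodes a protease, was at 6.63 to 13.0 in Lean-LF 1, Lean-LF 2 and GDM-LF 3 and at 624 to 1598 in the other 9 libraries. Agtr1b (chr2 105149020 to 105224295), an angiotensin II receptor, was at 14.4 to 21.4 in the library numbered 2 of every group and at 353 to 1112 in the other 8, a complete split by replicate number. The carbonic anhydrase Car3 was at 0.46 to 0.64 in 3 libraries and at 5.52 to 26.5 in 9, and the interferon-induced gene Ifit1 at 0.83 to 3.82 in 7 and 21.9 to 39.2 in 5. Hba-a1, which overlaps Hba2 and is uncertain, was the other. Fam111a and Car3 were at the high level in all 6 HFS and in 3 of 6 LF libraries (limma unadjusted p for diet 0.00844 and 0.0212), Ifit1 in 1 HFS and 4 LF libraries (0.0376) and Hba-a1 in all 6 Lean and 3 GDM libraries (0.00726 for the dam). No cause was tested for these levels.

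One split unlike the real one, with Lean-LF 3, Lean-HFS 3, GDM-LF 1 and 2 and GDM-HFS 2 and 3 against the rest, called 7 genes by limma. Fam111a was higher in the first set by 3.10, Anxa13 by 1.76, the glucocorticoid-induced gene Fkbp5 by 0.75, Ak1 by 0.60, Spata13 by 0.43 and the transcription factor Foxo3 by 0.39, and the cytokine signalling inhibitor Cish was lower (-1.20), with limma adjusted p between 2.86e-05 and 0.0462.

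A hypothesis was that offspring with nearby animal numbers share litters or handling and so deviate together. Over 18 pairs of libraries of 1 kind of dam and different diets, the correlation of their deviations fell as the numbers grew apart (Spearman rho -0.295, exact one-sided p = 0.124 over 1296 assignments). The 3 Lean-LF libraries each correlated best with the Lean-HFS library of the same replicate number (r = 0.0744, 0.0607 and 0.116), which was seen before it was asked and not tested alone. The 8 pairs within 5 numbers had a mean r of 0.0134 and the others of -0.011. Shared litters may thus exist without being seen, and these libraries do not settle it.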
